A study of Ovis aries with 24 samples.

How the data were processed

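Skeletal muscle RNA from cross-bred sheep was hybridised, as biotin-labelled cRNA made from 5 µg of total RNA, to a bovine Affymetrix GeneChip, per the labels. The 24 arrays form 12 groups of 2. Longissimus dorsi (LD), a back muscle, was measured in 4 genotypes at the callipyge locus at birth (T0) and at 11 to 12 weeks of age (T12). The labels place the T0 lambs within 5 days of birth. Supraspinatus (SS), a shoulder muscle, was measured at T12 in genotypes CN and NN. The muscle coded SM and semitendinosus (ST), from the hind limb, were measured at T12 in genotype NN. The labels give conflicting names for SM, so the code is kept. The genotypes are the homozygote CC, the paternal heterozygote CN (which carries the callipyge trait), the maternal heterozygote NC and the wild type NN. Some T12 labels also carry the word birth. The age code in the sample titles was used.

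The deposited values are linear intensity per probe set, made with the MAS5 algorithm per the submitters' processing notes, whose version is not given in the sources used here. On every array the 2% trimmed mean signal lay between 199.918 and 199.929, so the authors' scaling brings each array to one common level. Detection calls were not used here. Of 579072 values, 4295 were at or below 1 and were set to 1 before log2 was taken. The median signal per array was 47.4 to 59.7 and the highest was 27592.8 to 47009.9. Precision is limited by the number of arrays and by signal over background, and sheep transcripts can bind bovine probes less well than bovine ones.

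The labels call the 2 arrays of a group technical replicates. Their log2 values were averaged, and each group entered the fits as 1 value. Log2 values of the 2 arrays of a group correlated with r between 0.974 and 0.988 over probe sets with mean log2 signal above 8. Dimmer probe sets were noisier. In LD the SD between genotype means expected from the technical arrays was 0.154 in the brightest of 4 equal classes of signal. It was 0.717 in the dimmest. At most 0.336% of values were identical, so no pair was the same scan. The labels' protocols describe LD of 8 male lambs, 4 for each of a pair of genotypes, while arrays were made for 4 genotypes, so how many animals stand behind an array stays unknown. The p-values therefore measure the spread between group values, and a difference between single animals or pools cannot be separated from one of genotype.

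Tests used limma version 3.58.1 in R version 4.3.3 (lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05, per probe set). The 12 group values were fitted with 8 cells, in which CC, NC and NN of LD at each age were taken as 3 values of one cell. This leaves 4 residual degrees of freedom (prior degrees of freedom 6.88), and the groups with a single value are assumed to vary like the 3 genotypes in LD. Contrasts were CN against the other genotypes in LD at T12 and at T0, T12 against T0 in the other genotypes, the interaction of both, CN against NN in SS, the difference between that and the LD contrast, an F test over 4 muscles, and SS against SM and ST. NC and CC were compared with NN over the 8 LD groups with age as a covariate (3 residual degrees of freedom, prior 7.18).

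Of 24128 probe sets, 112 control probe sets were left out and 15613 were tested, those above the median log2 signal of all probe sets in at least 1 group. Gene names came from the platform annotation of 2016. Of all probe sets 13292 had 1 symbol, 86 had several and 10750 had none, and no gene was named from a probe set with several. The tested probe sets with 1 symbol numbered 9957 and covered 7481 symbols, of which 7062 also occur in the RefSeq gene table of the sheep assembly ARS-UI_Ramb_v3.0. No coordinates are given, because no genome was used here.

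Gene lists were tested with camera on the probe set of highest mean signal per symbol, with a preset correlation between genes of 0.01, and again with an estimated correlation. The 20 lists held 602 genes, of which 454 were measured. They cover the DLK1-DIO3 imprinted cluster, fast-fibre contractile, slow-fibre contractile, embryonic and neonatal muscle, glycolysis and glycogen, oxidative phosphorylation, TCA cycle, fatty acid uptake and oxidation, and adipocyte markers. The others are extracellular matrix and fibroblast, endothelial, red blood cell, immune cell, and nerve, Schwann and satellite cell markers, proliferation, protein breakdown, growth signalling, HDAC, MEF2 and calcium or cAMP signalling, ribosomal proteins, and stress and immediate early genes. A list needed 5 measured members, which left 19 tested, since the imprinted cluster had 4. IGF2 is in the embryonic and the growth list.

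Genes were named by rule. In each comparison these were the 12 largest positive and the 12 largest negative changes past the threshold, with 1 probe set per symbol, or the 10 of smallest p where fewer than 10 passed. Measured members of the imprinted cluster were named in the callipyge and genotype comparisons, along with up to 4 members of smallest p in each list described. Groups, tests, lists, the naming rule and the alternatives were chosen before the data were examined, except where the text says otherwise. The alternatives were arrays as separate samples with and without the array number as a block, quantile normalization, no filter or a 75th percentile filter, an offset of 32 before log2, no intensity trend, only the groups compared, other comparators, an estimated correlation, and leaving out each array. 5 further changes were added after the data were seen.

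Whether the array number pairs groups was checked on deviations from group means, over probe sets with mean log2 signal above 8. In LD at T12 all 6 pairs of groups correlated above 0.1 (r 0.371 to 0.544) and in the 3 other muscles of genotype NN all 3 pairs did (0.107 to 0.384). Over all 12 groups 33 of 66 pairs did (−0.411 to 0.544). The pairing comes from the data, since the labels give only a number. Averaging both arrays of a group removes it.

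The fits were tested on simulated data with 100 probe sets changed by 1 and 100 by 2 log2 units among 15613. For CN in LD, 22% and 56% were recovered at T12 and 16% and 64% at T0. For age 41% and 78% were recovered, for SS against SM and ST 15% and 50%, and for CN in SS 6% and 38%. False calls were 5 of 83, 3 of 83, 10 of 129, 6 of 71 and 3 of 47 calls in the same order. All 12 groups were simulated with the same spread, so the assumption that groups with a single value vary like the LD genotypes was not tested. A simulated shift of −0.6 in the 12 slow-fibre genes gave camera an adjusted p of 7.21e-21 with the preset correlation and 0.0659 with the estimated correlation, and 0 of 18 other lists were called. The simulated genes varied independently of each other, so this does not test the preset correlation where genes of a list move together.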

Results

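Gene expression was measured in skeletal muscle of sheep that carry or lack the callipyge mutation, which causes muscle enlargement after birth in animals that inherit it from the father only. The study asked which transcripts go with the enlargement and which go with a change of fibre type. LD was sampled from CC, CN, NC and NN lambs at T0 (within 5 days of birth) and T12. SS was sampled from CN and NN lambs at T12, and SM and ST from NN lambs at T12. The age in days of each T0 group is not known here, so it cannot be told apart from genotype. Each of the 12 groups has 2 technical arrays, averaged to 1 value. Median signal was 47.4 to 59.7 per array after scaling to a trimmed mean near 200, and 15613 probe sets were tested. Changes are log2 differences of MAS5 signal with the standard error of the limma fit. Where the dimmer side lies under 47.4, the lowest array median, it may not be above background, and the size of the change is uncertain.

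The genes at the callipyge locus were examined first, since their levels follow the inherited allele. DLK1, a paternally expressed membrane protein of the Notch ligand family, had a signal of 9573 in LD of CN lambs at T12 (arrays 11364.3 and 8064.3). CC, NC and NN gave 2818, 965.2 and 1044 at that age. At T0 the CN value was 4093 against 1390, 1106 and 1286. MEG3, a maternally expressed noncoding RNA, was highest in the other genotypes that carry the mutation, with 13367 in CC and 15773 in NC at T0 against 1350 in NN and 3709 in CN. At T12 the MEG3 signals were 12867, 13032, 358.2 and 2397 in the same order. In SS DLK1 was at 1220 in CN and 1217 in NN, and MEG3 at 547.9 and 358.3. The NN signals of DLK1 and MEG3 were 945.0 and 236.3 in SM and 1082 and 390.6 in ST.

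**Figure D1:**
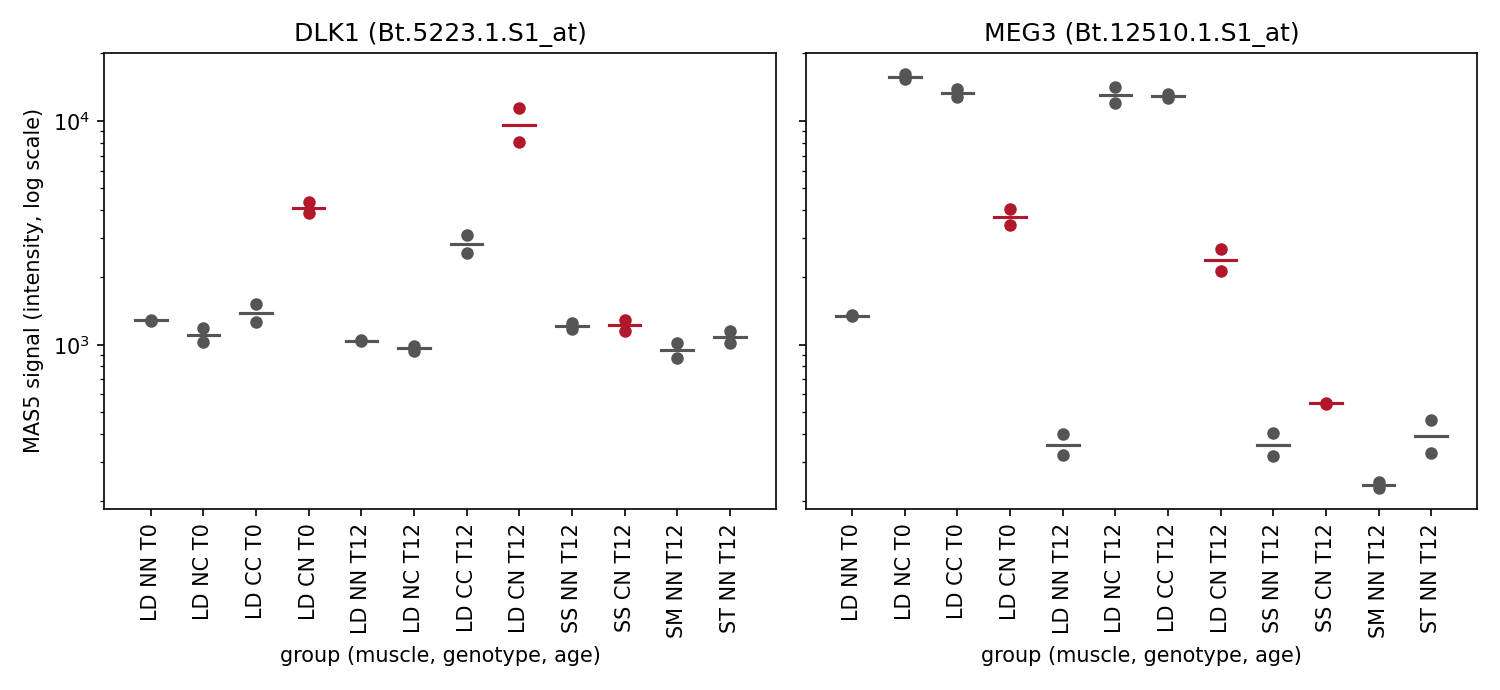
MAS5 signal on a log axis of DLK1 and MEG3 in the 12 groups, with each point 1 technical array, each bar the mean of the 2 arrays on the log scale and CN groups in red. DLK1 in LD is highest in CN, 4093 at T0 and 9573 at T12, and MEG3 is highest in NC and CC, between 12867 and 15773.

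MEG3 rose in NC over NN in LD by 4.37 ± 0.34 (SE, limma adjusted p = 0.00104) over both ages and in CC over NN by 4.24 ± 0.34 (adjusted p = 0.00139). A second MEG3 probe set rose by 2.37 ± 0.14 and 2.31 ± 0.14 (adjusted p = 1.58e-04 and 2.05e-04). These 2 probe sets were the only calls in each comparison, out of 660 and 852 probe sets at unadjusted p under 0.05. Another MEG3 probe set gave 1.59 and 1.68 (adjusted p = 0.126 and 0.0854), and the other 2 gave 0.75 and 0.91 in NC and 0.35 and 0.76 in CC, none passing. Without LD NC T12 replicate 1, 4 probe sets were called for CC.

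DLK1 did not pass in either comparison, with −0.17 ± 0.33 in NC (adjusted p = 0.995) and 0.77 ± 0.33 in CC (adjusted p = 0.886). The adaptor subunit PPP2R5C gave 0.29 and 0.28, and the tRNA synthetase WARS1 0.07 and 0.16. WARS1 in NC turned to −0.02 without LD NC T12 replicate 2 and −0.05 without LD NN T12 replicate 1, and in CC to −0.06 without LD CC T0 replicate 2. On single arrays, ZNF329 in NC was −1.47 without LD NC T0 replicate 2 and RAB3GAP2 1.24 without LD NN T0 replicate 2. The other genes of smallest p in NC, none passing, were MICU3, a regulator of mitochondrial calcium uptake, at −1.32 (adjusted p = 0.126), ID1 at −0.80, the interferon-induced IFI6 at 1.38, ZNF329 at −2.28, ACADM at −0.94, LOC618541 at −2.36, LOC407145 at 1.87, RAB3GAP2 at 2.12 and ADSS1 at 0.70. Of these ZNF329, LOC618541, LOC407145 and RAB3GAP2 had a dimmer signal of 13.9 to 20.9. Those in CC were ACADM, a dehydrogenase of fatty acid oxidation, at −1.37 (adjusted p = 0.0854), the class II antigen BOLA-DQB1 at 2.12, BLVRB at −1.68, SARS1 at −0.87, MYBPH at 1.11, ID1 at −0.70, ADSS1 at 0.80, MRPS36 at −0.90 and LOC407145 at 1.94, the last with a signal of 18.6 in NN.

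In LD at T12, CN lambs were set against the 3 other genotypes, and 28 probe sets passed, 6 higher and 22 lower in CN, of which 22 have 1 symbol. DLK1 rose by 2.76 ± 0.45 (adjusted p = 0.0492, 1 CN value against 3). The muscle lysine methyltransferase METTL21E rose by 2.34 ± 0.33 (adjusted p = 0.0366), from 195.7 to 992.4 in signal. The spindle protein TPX2 rose by 2.01 ± 0.33, PLCL2, a phospholipase C-like protein, by 1.44 ± 0.24, and PARK7, which protects against oxidative stress, by 1.26 ± 0.16. Among lower genes were slow skeletal troponin T, TNNT1 (−0.97 ± 0.14, adjusted p = 0.0366), and the slow myosin heavy chain MYH7 (−0.89 ± 0.14, adjusted p = 0.0492).

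Also lower in CN at T12 were VEGFA, a growth factor for blood vessels, at −0.96, ALAD, an enzyme of haem synthesis, at −1.26, the Wnt inhibitor FRZB at −1.35 and the milk protein CSN2 at −1.48. The proteoglycan KERA was at −1.95, the kinase PRKG1 at −1.96, the trafficking protein TRAPPC9 at −2.14 and the scaffold MPDZ at −2.55. The mitochondrial enzyme SHMT2 and the immune transcription factor IRF8 were both at −2.58 and TKDP1 at −2.61. The last 7 had CN signals of 10.1 to 49.7, against 59.4 to 223.1 in the other genotypes. All of them but PRKG1 (49.7) lay under 47.4, the lowest array median. SHMT2 and MPDZ turned to 0.03 and 0.65 without LD CN T12 replicate 1, and TRAPPC9 to 0.19 without LD CN T12 replicate 2. TKDP1 was −0.82 without replicate 1 and PRKG1 −1.15 without replicate 2 of the same group.

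Outside the naming rule, and chosen after their values were seen, 4 more genes fell at T12. FSCN1 at −2.50, the lymphatic marker LYVE1 at −2.26 and AKR1C4 at −1.62 did so on a probe set that is not the brightest of the gene, and ATP5IF1, an inhibitor of ATP synthase, was at −0.85. The CN signals of FSCN1 and LYVE1 were 14.1 and 15.0, so the size of these changes is uncertain. Of the 17 named genes 9 have other tested probe sets, 10 in all, of which 8 had the same direction, 2 the opposite and 0 passed. CSN2 was 1.16 and TKDP1 0.45 on the other probe set, PLCL2 0.11, DLK1 0.59 (adjusted p = 0.666), METTL21E 1.94 and TPX2 2.02.

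The adjusted p of the 17 genes named by rule for their size lay between 0.0238 and 0.0495, and 0 of the 17 passed in each of the 24 fits that left out an array. Calls were lost in 1 such fit for IRF8, 3 for PARK7, 3 for VEGFA, 20 for DLK1 and 22 for TPX2. Without a CN array, CN enters as 1 array and the SE misses its larger technical spread. Counts from those fits, here and at T0, can therefore be too high and are no sign of more changed genes. The count became 218 and 414 without replicates 1 and 2 of LD CN T12, 1 and 14 without those of LD CC T0, and 7 and 11 without those of LD NC T0. It was 7 and 11 without those of LD NN T0, 12 and 2 for LD NC T12, 7 and 16 for LD NN T12 and 18 for either array of SS CN T12. Without replicate 1 it was 3 for LD CC T12, 13 for SM NN T12, 15 for SS NN T12 and 18 for ST NN T12, and without LD CN T0 replicate 2 it was 18.

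MEG3 in CN at T12 was −0.71 ± 1.78 against the 3 genotypes together (adjusted p = 0.948) and 2.74 against NN alone (adjusted p = 3.1e-05). At T0 these values were −0.83 ± 1.78 (adjusted p = 0.921) and 1.46 (adjusted p = 0.0034). WARS1 was 0.20 at T12 and −0.14 at T0. PPP2R5C was 0.01 and −0.13, and its T12 value was −0.14 without NN in the comparator. PPP2R5C at T12 was also negative without LD CN T12 replicate 1 (−0.21), LD NC T12 replicate 2 (−0.02) or LD NN T12 replicate 2 (−0.02), and WARS1 at T0 was 0.00 without LD CC T0 replicate 2. The MEG3 values against NN compare 1 group value with 1 other. Their p rests on spread taken from other groups, with 1 residual degree of freedom, the difference between the age steps of CC and NC. In the test against the 3 genotypes together, the MEG3 difference among CC, NC and NN counts as spread, so it could hardly call MEG3. On another MEG3 probe set that responds to genotype CN lay below NN, with 226.6 against 231.7 at T0 and 122.5 against 176.8 at T12. CN was above NN at both ages on 2 of the 5 MEG3 probe sets.

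Slow-fibre contractile genes fell together in CN at T12, with a median of −0.60 over 12 genes and 12 of 12 negative (adjusted p = 1.11e-10, and 0.282 as the adjusted p with an estimated correlation). Over all genes 2 members were called, TNNT1 and MYH7, and 9 were when adjusted over the list alone, among them the slow light chains MYL3 (−2.19 ± 0.42, adjusted p = 0.073) and MYL2 (−0.58 ± 0.14, adjusted p = 0.14). Fast-fibre contractile genes were not called (adjusted p = 0.161), with a median of −0.00, a mean of 0.18 and a test direction upward. Their members MYLK2 and ACTN3 had 1.60 ± 0.48 and 0.44 ± 0.15, neither passing. Of the 16 genes of this list 10 were measured. MYH1 was the only fast myosin heavy chain among them, so a rise of MYH2 or MYH4 would not be seen. The log2 ratio of 3' to 5' GAPDH probe sets, which changes with RNA quality, was −0.0332 and 0.0849 on the LD arrays of CN at T12. It was 0.0433 and 0.0663 on those of CC and 0.187 to 0.246 on those of NC and NN. The ratio therefore moves with each list change of CN against NC and NN at T12, while CC lay inside the range of CN. The same ratio for actin, 0.0473 and 0.0360 in CN, lay inside the range of NC and NN (0.0314 to 0.294).

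Fuel genes also moved. Fatty acid genes fell (median −0.38, 22 of 26 negative, adjusted p = 2.31e-07, and adjusted p = 0.282 with an estimated correlation), with 0 called over all genes and 9 when adjusted over the list alone, among them HADHA at −0.999, ACADVL at −0.77, ETFB at −0.87 and the lipase LPL at −1.05. Oxidative phosphorylation fell by a median of 0.22 (67 of 72 negative, adjusted p = 1.22e-08, and adjusted p = 0.385 with an estimated correlation). The TCA cycle median was −0.19 (adjusted p = 0.0184, and adjusted p = 0.385 with an estimated correlation), and that call ended without LD CN T12 replicate 2 (−0.17). Glycolysis and glycogen genes rose (median 0.19, 15 of 20 positive, adjusted p = 5.5e-05, and adjusted p = 0.385 with an estimated correlation), with PGM1 at 0.45 ± 0.14. In these last 3 lists 0 genes were called over all genes and 0 when adjusted over the list alone.

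Extracellular matrix and fibroblast markers fell (median −0.36, 27 of 30 negative, adjusted p = 1.2e-06, and adjusted p = 0.385 with an estimated correlation), with 0 called over all genes and 5 when adjusted over the list alone, among them COL1A2 at −0.78, FN1 at −0.995, COL1A1 at −0.92 and FMOD at −1.06. Endothelial markers had a median of −0.27 (adjusted p = 0.0337, and adjusted p = 0.417 with an estimated correlation). That call ended without LD CN T12 replicate 1 (−0.12) or 2 (−0.29), LD NN T0 replicate 2 (−0.28), LD CC T12 replicate 1 (−0.31) or LD NN T12 replicate 2 (−0.27). Protein breakdown genes, mostly proteasome subunits, rose (median 0.25, 29 of 34 positive, adjusted p = 3.7e-07, and adjusted p = 0.282 with an estimated correlation), with PSMB5 at 0.45 and PSMC6 at 0.51. Ribosomal protein genes were lower (median −0.14, 61 of 62 negative, adjusted p = 6.08e-05, and adjusted p = 0.536 with an estimated correlation), but not past the threshold with quantile normalization (−0.05) or without LD CN T12 replicate 2 (−0.05). None of the members of these last 3 lists were called, over all genes or adjusted over the list alone.

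Lists not called at T12 were embryonic and neonatal muscle (median −0.50, adjusted p = 0.161), adipocyte markers (−0.36, 0.0961), immune cell markers (−0.35, 0.175), nerve, Schwann and satellite cell markers (−0.12, 0.826), proliferation (−0.17, 0.58), growth signalling (−0.04, 0.492), HDAC, MEF2 and calcium or cAMP signalling (0.01, 0.384), stress and immediate early genes (0.04, 0.399) and red blood cell markers (median −0.11, mean 0.01, adjusted p = 0.874). Within them, adjusted over the list alone, the calls were the adipocyte hormone ADIPOQ at −2.03, the calcineurin inhibitor RCAN1 at −1.12, TPX2, and in growth signalling IGFBP4 at −1.31, FGFR4 at −1.92 and FST at −0.68. TPX2 alone passed over all genes.

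**Figure D2:**
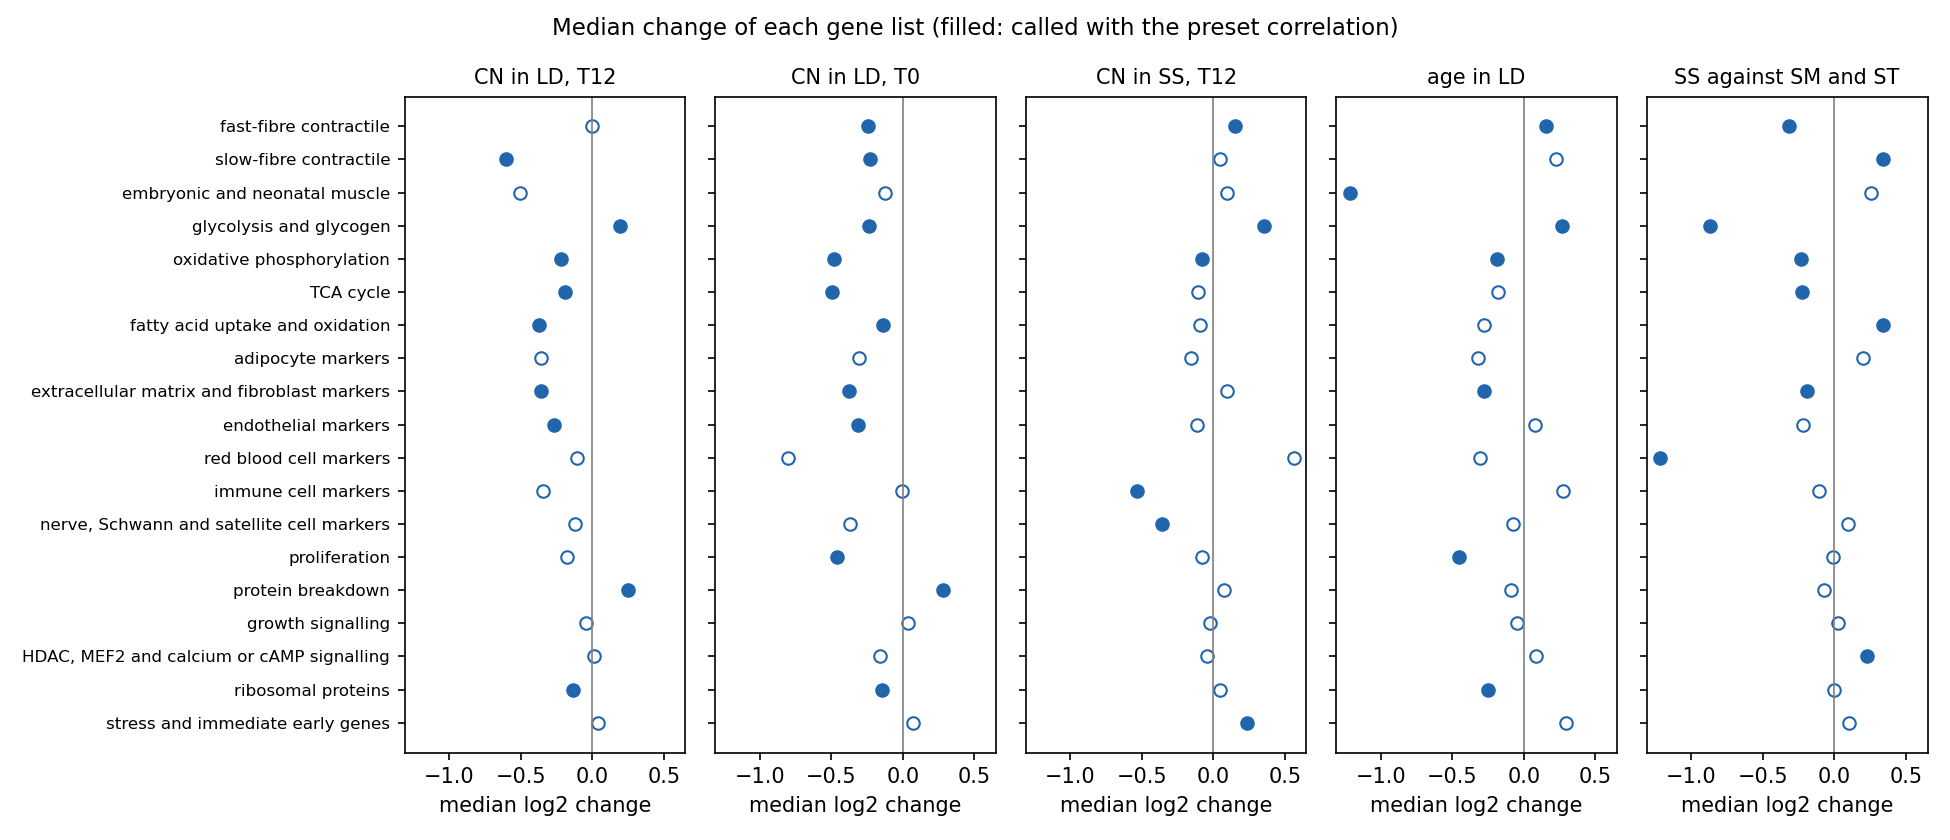
Median log2 change of 19 gene lists in 5 comparisons, 1 point per list, filled where camera with the preset correlation called the list. Slow-fibre genes are at −0.60 for CN in LD at T12 and 0.34 for SS against SM and ST, ribosomal proteins at −0.15 for CN in LD at T0 turn to 0.06 with quantile normalization, and no list is called with an estimated correlation.

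At birth, before the muscle enlargement is visible, 27 probe sets differed in LD of CN lambs, 20 higher and 7 lower, of which 19 have 1 symbol. The tubulin TUBB2B rose by 2.36 ± 0.26 (adjusted p = 0.0145), from 965.4 to 4941 in signal, while its other probe set gave 0.02 (adjusted p = 0.992). RRAD, a small GTPase that restrains calcium channels, fell by 2.00 with an SE of 0.21 (adjusted p = 0.0145). VMP1 at 1.69 ± 0.22 (adjusted p = 0.0287), GABARAPL1 at 1.35 ± 0.21 and RETREG1 at 1.12 ± 0.18 also rose. Each has a known part in autophagy, for which no list was tested. DLK1 was 1.71 ± 0.45 and did not pass over all genes (adjusted p = 0.148). Its SE pools both ages and so holds the DLK1 difference at T12 between CC (2818) and NC and NN (965.2 and 1044). At T0 these 3 genotypes lay between 1106 and 1390, so this test is weak for DLK1.

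Also higher in CN at T0 were the translation factor EIF4E3 at 2.07, ERRFI1, an inhibitor of the epidermal growth factor receptor, at 1.71, the chaperone HSPA2 at 1.49, the peroxisomal protein PXMP2 at 1.46 and the actin-binding TWF2 at 1.41. The ubiquitin ligase adaptor ASB11 was at 1.39, APBB2 at 1.28 and CRCP at 1.20. Lower were the DNA repair gene XRCC4 at −3.21, the dystrobrevin DTNA at −2.79, PTER at −1.36 and COX7A1, a muscle subunit of cytochrome oxidase, at −0.88 ± 0.13 (adjusted p = 0.0463). The CN signals of XRCC4 and DTNA were 6.90 and 12.7, so the size of their changes is uncertain. DTNA was −1.24 without LD CN T0 replicate 2 and no longer passed (adjusted p = 0.0883). Outside the naming rule, and chosen after its value was seen, the mitophagy receptor BNIP3 was higher by 1.47 (adjusted p = 0.0487) on the less bright of its probe sets. Of the 17 named genes 7 have other tested probe sets, 10 in all, of which 8 had the same direction and 1, of EIF4E3 at 2.02, passed.

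TUBB2B and RRAD passed in each of the 24 fits without an array and the other 15 named genes did not. The count was 268 and 252 without replicates 1 and 2 of LD CN T0, 5 and 6 without those of LD CC T0, 7 and 6 for LD NC T0 and 9 and 6 for LD NN T0. It was 5 and 7 for LD CC T12, 9 and 6 for LD NN T12, 54 without LD CN T12 replicate 1, 3 without LD NC T12 replicate 2 and 55 without SS NN T12 replicate 2.

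Oxidative phosphorylation genes were lower as a group at T0, with a median of −0.48 and 72 of 72 negative (adjusted p = 1.55e-39, and adjusted p = 0.141 with an estimated correlation). COX7A1 was called over all genes and 60 members were when adjusted over the list alone, among them ATP5MC1 at −0.73, NDUFS3 at −0.63 and ATP5MF at −0.62. The list kept its call with quantile normalization, while the fast-fibre, slow-fibre, glycolysis and ribosomal lists below did not. The CN arrays at T0 had median signals of 48.1 and 47.4, against 50.1 to 52.9 on the other birth arrays. How far array scaling adds to the size of the change stays open. TCA cycle genes fell by a median of 0.49 (17 of 18 negative, adjusted p = 1.16e-11, and adjusted p = 0.141 with an estimated correlation), with 0 called over all genes and 15 when adjusted over the list alone, among them SUCLA2, IDH2 at −1.16, SDHC and PDHA1. Protein breakdown genes rose (median 0.28, 32 of 34 positive, adjusted p = 1.03e-10, and adjusted p = 0.141 with an estimated correlation). Of these GABARAPL1 was called over all genes and 2 were when adjusted over the list alone, the other being PSMD11 at 0.62.

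Other lists that fell at T0 were extracellular matrix and fibroblast markers (median −0.38, adjusted p = 7.68e-05, and adjusted p = 0.451 with an estimated correlation) and proliferation (−0.46, adjusted p = 0.00195, and adjusted p = 0.367 with an estimated correlation), where CKS2 at −1.55, UBE2C at −1.16 and STMN1 at −0.79 passed when adjusted over the list alone. Endothelial markers had a median of −0.31 (adjusted p = 0.00827, and adjusted p = 0.389 with an estimated correlation), with CDH5 at −0.95, TIE1 and VWF passing when adjusted over the list alone. That endothelial call ended with the 75th percentile filter (−0.24). Over all genes 0 members of these 3 lists were called, and 0 matrix genes were when adjusted over the list alone.

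Fast-fibre genes had a median of −0.24 at T0 (adjusted p = 2.05e-04, and adjusted p = 0.389 with an estimated correlation), slow-fibre genes −0.23 (adjusted p = 0.0055, and adjusted p = 0.454 with an estimated correlation) and glycolysis and glycogen −0.24 (adjusted p = 0.00623, and adjusted p = 0.454 with an estimated correlation). All 3 calls ended with quantile normalization, at −0.08, −0.14 and −0.04. Ribosomal protein genes were at −0.15 (adjusted p = 7.68e-05, and adjusted p = 0.454 with an estimated correlation) and turned to 0.06 with quantile normalization. Fatty acid genes were at −0.14 (adjusted p = 0.00799, and adjusted p = 0.419 with an estimated correlation). Without LD CN T0 replicate 1 the slow-fibre, glycolysis, fatty acid and ribosomal calls ended, at −0.13, −0.10, −0.13 and −0.03, and the number of lists called fell from 11 to 7. Over all genes 0 members of these lists were called, and adjusted over the list alone 2 fast-fibre genes were lower, 3 glycolysis genes lower and 1 higher, 2 fatty acid genes lower, and 0 slow-fibre and 0 ribosomal genes passed.

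Lists not called at T0 were embryonic and neonatal muscle (median −0.12, adjusted p = 0.89), adipocyte markers (−0.31, 0.655), red blood cell markers (−0.80, 0.0743), nerve, Schwann and satellite cell markers (−0.37, 0.329), growth signalling (0.03, 0.375), HDAC, MEF2 and calcium or cAMP signalling (−0.16, 0.483), stress and immediate early genes (0.07, 0.0563) and immune cell markers (median −0.01, mean 0.05, adjusted p = 0.559). Adjusted over the list alone, 5 stress genes were called higher, namely the transcription factor MYC at 1.75, GADD45A at 1.36 and the chaperones HSPH1 at 0.77, HSP90AA1 at 0.62 and HSPA1A at 0.47, and 1 lower, IER3 at −1.08. In growth signalling DDIT4 at 0.85 was called this way, and over all genes none of these passed.

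**Figure D3:**
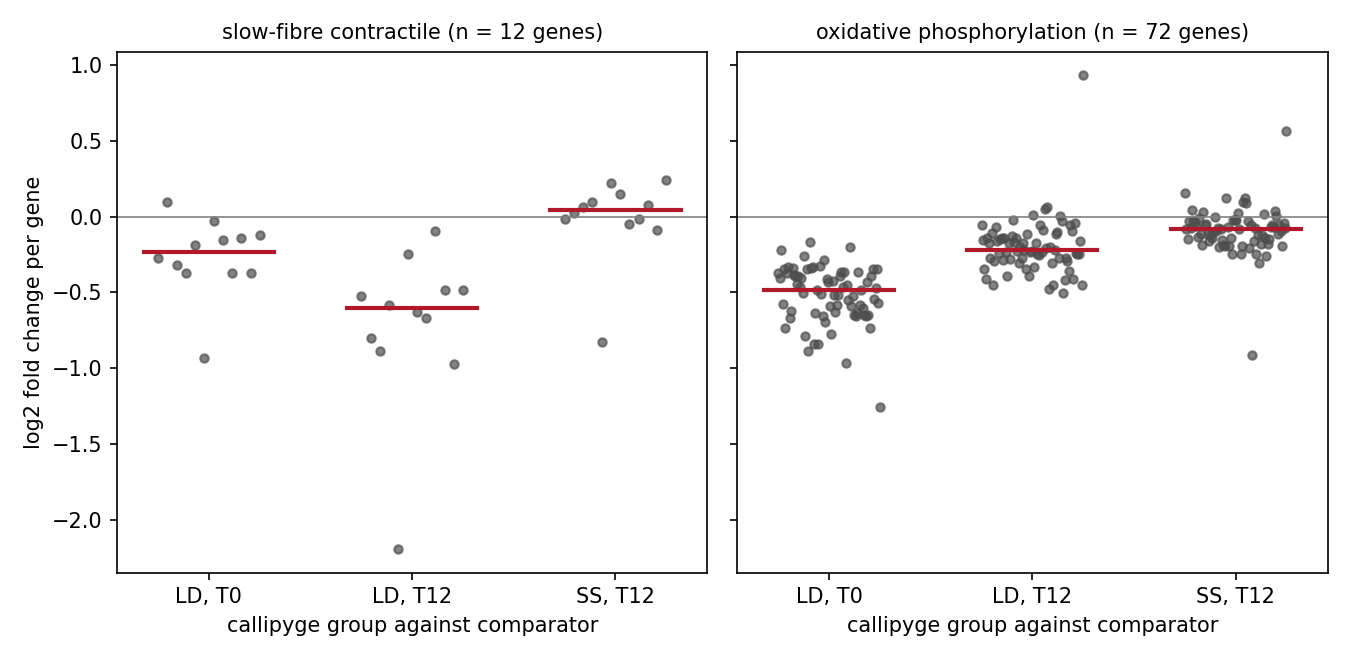
Log2 fold change of each measured gene in the slow-fibre (12 genes) and oxidative phosphorylation (72 genes) lists for CN in LD at T0, LD at T12 and SS at T12, with the median as a red line. Medians are −0.23, −0.60 and 0.05 for slow-fibre genes and −0.48, −0.22 and −0.08 for oxidative phosphorylation.

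Growth from birth to 11 to 12 weeks in the 3 genotypes other than CN changed 1831 probe sets, 924 higher and 907 lower at T12. Embryonic and neonatal muscle genes fell as a list, with a median of −1.21 over 13 genes and 7 called lower (adjusted p = 9.37e-05, and adjusted p = 0.45 with an estimated correlation). Embryonic myosin MYH3 was among the 7 (−2.98 ± 0.55, adjusted p = 0.00629). The collagens COL11A1 (−3.46 ± 0.40) and COL2A1 (−2.55 ± 0.30) fell on their brightest probe set, while the others gave −1.36, −1.18 and 0.77 for COL11A1 and −0.20, 0.74 and 0.16 for COL2A1. NMRK2, a muscle kinase of NAD synthesis, fell from 10686 to 1927 (−2.47 ± 0.13, adjusted p = 1.97e-05). The T cell genes CD3G at 2.62 ± 0.58 and CD8A at 2.34 ± 0.51 rose, as did the class II antigens BOLA-DRA at 2.43 ± 0.19 and BOLA-DQB1 at 2.40 ± 0.58, though the immune cell list did not pass (adjusted p = 0.0938, 9 of 17 positive). FBXO32, a ubiquitin ligase of muscle wasting, rose by 2.69 ± 0.63 (adjusted p = 0.0193).

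Others that rose with age were the junction protein CGN at 3.09, ARRDC2 at 2.90, the ubiquitin-like UBD at 2.87, LOC100335205 at 2.69, CMBL at 2.62, LRRC2 at 2.57 and RASD1 at 2.42. Others that fell were the triglyceride enzyme DGAT2 at −3.19, CHAC1 at −3.12, XIST at −2.87, the matrix protein CRTAC1 at −2.80, the proteoglycan GPC1 at −2.79, the chaperone FKBP11 at −2.66, the serine synthesis enzyme PHGDH at −2.59 and PDXK at −2.55. Of the 24 named genes 8 have other tested probe sets, 14 in all, of which 10 had the same direction, 4 the opposite and 5 passed. In 14 of the 24 the dimmer age had a signal under the lowest array median, CD3G (8.41 at T0 and 51.8 at T12) and CD8A (8.64 and 43.7) among them. In leave-one-out fits 18 of the 24 named genes passed each time and the count was 1225 to 1910. UBD passed neither without LD NC T0 replicate 1 (adjusted p = 0.0619) nor without LD NC T12 replicate 2 (0.0698), CD3G and FKBP11 not without LD CC T12 replicate 2 (0.0579 and 0.0539) and CD8A not without LD NC T12 replicate 2 (0.0522). PHGDH was lost without 3 arrays, namely LD CC T0 replicate 1, LD CC T12 replicate 1 and LD NN T12 replicate 2 (0.0615, 0.0502 and 0.0656), and LOC100335205 without 8 arrays.

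In the embryonic and neonatal list 7 genes were also called when adjusted over the list alone, among them the growth factor IGF2 (−1.78 ± 0.12), MEST at −1.43 and neonatal myosin MYH8 at −2.13. Ribosomal protein genes fell (median −0.25, 22 called, 30 adjusted over the list alone, adjusted p = 1.77e-11, and adjusted p = 0.45 with an estimated correlation), RPL29 having the smallest p. Matrix and fibroblast genes fell (−0.28, 9 called, 12 lower and 1 higher adjusted over the list alone, adjusted p = 9.37e-05, and adjusted p = 0.45 with an estimated correlation), with the collagen chaperone SERPINH1 at −1.64 and COL1A1 at −1.49.

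Proliferation genes fell with age (median −0.45, 5 called, 6 adjusted over the list alone, adjusted p = 0.00397, and adjusted p = 0.45 with an estimated correlation), among them CKS2, STMN1 and CDC20. Oxidative phosphorylation had a median of −0.19, with 17 lower and 1 higher over all genes and 25 lower and 4 higher adjusted over the list alone (list adjusted p = 5.18e-06, and adjusted p = 0.45 with an estimated correlation), COX7A2 at −1.63 leading. Glycolysis and glycogen genes rose (0.27, 6 called, 12 adjusted over the list alone, adjusted p = 1.32e-04, and adjusted p = 0.45 with an estimated correlation), PFKFB3 at 1.92 leading. Fast-fibre genes rose (0.16, 10 of 10 positive, 2 called, 2 adjusted over the list alone, adjusted p = 0.00338, and adjusted p = 0.45 with an estimated correlation), but not with quantile normalization (0.08).

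The 3' to 5' GAPDH ratio also moved with age and so with each of these lists, from 0.131 and 0.216 at T0 to 0.0433 and 0.0663 at T12 in CC and from between 0.246 and 0.307 to between 0.187 and 0.246 in NC and NN. The actin ratio of these genotypes overlapped between the ages, at −0.0700 to 0.196 at T0 and 0.0314 to 0.294 at T12. The 12 other lists were not called for age. Protein breakdown had a median of −0.09 and a mean of 0.08 (adjusted p = 0.774), and growth signalling −0.05 and 0.01 (0.774). Slow-fibre, TCA cycle, fatty acid, adipocyte and red blood cell lists had adjusted p = 0.145 each, with medians of 0.22, −0.18, −0.28, −0.32 and −0.30. Endothelial markers gave 0.08 (0.164), immune cell markers 0.27 (0.0938), nerve markers −0.07 (0.774), HDAC and MEF2 signalling 0.08 (0.528) and stress genes 0.30 (0.673).

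Whether the callipyge difference in LD changed with age was tested as an interaction, and limma called 0 probe sets, with 1396 at unadjusted p under 0.05. The smallest p belonged to RRAD, whose CN difference was 2.38 ± 0.30 higher at T12 than at T0 (adjusted p = 0.106). The others of smallest p, all with adjusted p = 0.197, were VMP1 at −1.90, CRCP at −1.50, the neuropeptide precursor TAC1 at −2.34, MUSTN1 at −2.99, GABARAPL1 at −1.71, CDK2AP1 at 1.56, the growth factor MDK at 3.71, ASB11 at −1.68 and PARK7 at 1.24. DLK1 was 1.05 ± 0.64, MEG3 0.12 ± 2.52, WARS1 0.34 and PPP2R5C 0.14. The SE of MEG3 again holds the MEG3 difference among CC, NC and NN, and that of DLK1 holds the DLK1 difference among them at T12. The count was 37 without LD CN T12 replicate 2, 4 without its replicate 1 and 1 without LD CN T0 replicate 2. Without LD CN T12 replicate 1 MEG3 turned to −0.04 and PPP2R5C to −0.08, and TAC1 was −1.43.

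In SS, which the labels give for CN and NN only, limma called 0 probe sets between these genotypes at T12, with 651 at unadjusted p under 0.05. The smallest p values, none passing, were those of DERL1, a protein of endoplasmic reticulum quality control (−2.71, adjusted p = 0.165), CD320 (2.51, 0.338), ZBTB44 (−3.92), the imprinted PEG10 (−2.63), PDXK (−2.90), MARS1 (1.62), the adaptor MYD88 (−3.32), NMRK2 (1.15), PTPRCAP (−1.84) and GRK6 (−2.05). In 9 of these 10 genes the dimmer genotype had a signal under the lowest array median. DLK1 was 0.00 ± 0.56, MEG3 0.61 ± 2.18, WARS1 −0.18 and PPP2R5C 0.11. The SE of MEG3 holds the MEG3 difference among the LD genotypes, so this test cannot show that MEG3 is alike in SS. The SE of DLK1 likewise holds the DLK1 difference among CC, NC and NN in LD at T12. On its brightest probe set both CN arrays (550.8 and 545) lay above both NN arrays (318.4 and 403.3), which are technical repeats. MARS1 was −0.06 without SS NN T12 replicate 1, PPP2R5C −0.13 without SS CN T12 replicate 1, and DLK1 −0.08 and −0.04 without replicate 2 of SS CN T12 and SS NN T12. Without SS CN T12 replicate 2 DERL1 was −0.23, ZBTB44 −1.77 and MYD88 −1.36, without its replicate 1 PTPRCAP was −0.15, and without SS NN T12 replicate 1 CD320 was 0.73. Other probe sets of CD320 gave −1.58 and 0.55. Leaving out replicate 1 or 2 of SS CN T12 gave 12 or 11 calls, and of SS NN T12 10 or 5.

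Gene lists in SS were tested too, with 1 group value for each genotype, so that each p rests on spread taken from the LD genotypes. Glycolysis and glycogen genes rose in CN (median 0.35, 16 of 20 positive, adjusted p = 7.61e-07, and adjusted p = 0.376 with an estimated correlation), with PGM1 at 0.49 and LDHA at 0.39. Immune cell markers had a median of −0.53 (adjusted p = 0.0163, and adjusted p = 0.374 with an estimated correlation), and nerve, Schwann and satellite cell markers −0.36 (adjusted p = 0.0156, and adjusted p = 0.374 with an estimated correlation), with the myogenic factor MYOD1 at −2.14. Fast-fibre genes were at 0.15 (adjusted p = 0.0109, and adjusted p = 0.656 with an estimated correlation), stress genes at 0.23 (0.0233, and adjusted p = 0.376 with an estimated correlation) and oxidative phosphorylation at −0.08 (0.0105, and adjusted p = 0.763 with an estimated correlation). In these 6 lists 0 genes were called over all genes, and MYOD1 was the 1 called when adjusted over the list alone.

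The glycolysis call in SS held in each leave-one-out fit and the other 5 did not. Without SS NN T12 replicate 2 the fast-fibre (0.15), oxidative phosphorylation (−0.07), immune (−0.55), nerve (−0.61) and stress (0.24) calls ended. Without SS CN T12 replicate 2 the fast-fibre (0.08), immune (−0.39), nerve (−0.39) and stress (0.25) calls did, without SS CN T12 replicate 1 those of oxidative phosphorylation (−0.01) and stress (0.22), and without SS NN T12 replicate 1 that of stress (0.18). The number of lists called fell from 6 to 2 without SS CN T12 replicate 2 and to 1 without SS NN T12 replicate 2. The fast-fibre call also ended with quantile normalization (0.08) and the nerve call without the filter (−0.19). Red blood cell markers had a median of 0.56 and a mean of 1.07 and did not pass (5 of 6 positive, adjusted p = 0.0661), nor did matrix and fibroblast markers (median 0.10, mean 0.17, adjusted p = 0.0585). Slow-fibre genes were not called (median 0.05, mean −0.01, test upward, adjusted p = 0.703), and 5 of the 12 had an SS signal above 29547, in the range of the brightest probe sets, in 1 genotype or both. The embryonic list had a median of 0.09 and a mean of −0.15 (test downward, adjusted p = 0.664), with PEG10 called when adjusted over the list alone. The others not called were the TCA cycle (median −0.11, adjusted p = 0.141), fatty acid genes (−0.10, 0.141), adipocyte (−0.15, 0.703) and endothelial markers (−0.11, 0.515), proliferation (−0.08, 0.752), protein breakdown (0.07, 0.195), growth signalling (−0.02, 0.763), HDAC and MEF2 signalling (−0.05, 0.211) and ribosomal proteins (0.04, 0.211).

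The difference between the callipyge effect in LD and in SS gave 0 calls in limma, with 775 at unadjusted p under 0.05. Genes of smallest p were IRF8 at −2.84, DERL1 at 2.63, PPP1R12C at −3.17, STARD5 at −3.31 and ZBTB44 at 4.67 (adjusted p = 0.341 each), then TAC1 at −2.18, PARK7 at 1.19, RTKN at −1.95, CD320 at −2.61 and TKDP1 at −3.07 (0.404 each). DLK1 was 2.75 ± 0.72 (adjusted p = 0.595), MEG3 −1.32, WARS1 0.38 and PPP2R5C −0.10. For MEG3 and DLK1 the difference among CC, NC and NN counts as spread here too. Against NN alone MEG3 was 2.13 and PPP2R5C 0.20. The count was 2 without either array of LD CN T12, 2 without SS CN T12 replicate 1 and 1 without its replicate 2. PPP2R5C was 0.12 without LD CN T12 replicate 2 and 0.14 without SS CN T12 replicate 1. Without SS CN T12 replicate 2 DERL1 was 0.15 and ZBTB44 2.53, without SS NN T12 replicate 1 RTKN was −0.92 and CD320 −0.83, and without LD CN T12 replicate 1 TAC1 was −1.27 and TKDP1 −1.28. TKDP1 was −1.89 without SS NN T12 replicate 2. Of 8 other probe sets of the 10 genes 6 had the same direction and 0 passed, with CD320 at 1.83 and 0.13.

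Muscles of differing fibre type were compared in NN lambs at T12, taking LD as the mean of CC, NC and NN. The F test over 4 muscles called 201 probe sets, with 1973 at unadjusted p under 0.05. It was 125 without LD NC T12 replicate 2, 383 and 378 without replicate 1 of SM and ST, 302 without ST replicate 2, and 302 and 333 without replicates 1 and 2 of SS NN T12. Each muscle against LD, chosen after the data were seen, gave 463 calls for SS (223 higher and 240 lower), 13 for ST (3 and 10) and 2 for SM (0 and 2).

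SS against SM and ST, 1 group value against 2, called 156 probe sets, 72 higher and 84 lower in SS. STAC3, part of the excitation-contraction coupling machinery, rose by 3.62 ± 0.21 (adjusted p = 2.99e-05), from 478.4 to 5876 in signal. The calcineurin regulators RCAN1 and RCAN2 rose by 1.74 ± 0.21 and 1.83 ± 0.37. MYBPH, a myosin-binding protein, was lower at −5.08 ± 0.46 (adjusted p = 6.58e-04), as were the lactate transporter SLC16A3 at −2.05 ± 0.34 and the collagen cross-linking enzyme LOX at −2.02 ± 0.34.

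Others higher in SS were LOC513055 at 3.24, LAPTM4B at 2.36, the mitochondrial ribosomal protein MRPS6 at 2.29, the acetate-activating ACSS1 at 2.11, ABLIM1 at 2.10, XPO4 at 1.93, LGI1 at 1.88, EPHX2 at 1.82 and the phosphatase PTP4A2 at 1.74. Others lower were WASHC1 at −2.94, IRF7 at −2.81, CD320 at −2.44, DNTTIP1 at −2.29, PDE9A at −2.20, SYNJ1 at −2.06, SLC38A7 at −2.01, ARF5 at −1.81 and RAB22A at −1.74. In 9 of the 24, all lower in SS, the SS signal lay under the lowest array median. In leave-one-out fits 13 of the 24 passed each time. Without SS NN T12 replicate 2 IRF7 was −0.30 and SLC38A7 −0.93, and without its replicate 1 CD320 was −0.66, WASHC1 −0.94, PDE9A −1.15, LOX −0.92, ARF5 −1.03 and RAB22A −0.57, none passing. Of 13 other probe sets of these genes 11 had the same direction and 7 passed. The count was 88 without LD NC T12 replicate 2, 103 without LD NN T12 replicate 2, and 255 and 275 without replicates 1 and 2 of SS NN T12.

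Glycolysis and glycogen genes were lower in SS (median −0.87, 18 of 20 negative, 9 called, 15 adjusted over the list alone, adjusted p = 6.84e-17, and adjusted p = 0.261 with an estimated correlation), with PGM1 at −1.62, PFKM at −1.31, LDHA at −1.02 and PGAM2 at −0.93. Slow-fibre genes were higher (0.34, 11 of 12 positive, 0 called, 4 adjusted over the list alone, adjusted p = 5.82e-06, and adjusted p = 0.295 with an estimated correlation), MYL6B at 2.13 and PLN at 1.21 being examples that did not pass over all genes. The SS signals in NN of MYL2 (36854), MYH7 (37229) and FHL1 (33097) lay above 29547, in the range of the brightest probe sets. Fast-fibre genes were lower (−0.32, adjusted p = 4.24e-04, and adjusted p = 0.394 with an estimated correlation), with ACTN3 at −0.96 called over all genes and 4 adjusted over the list alone. Fatty acid genes were higher (0.34, adjusted p = 2.66e-04, and adjusted p = 0.295 with an estimated correlation), with LPL at 1.69, ACAT1 at 0.81 and the fatty acid carrier CD36 at 1.09 called higher, the uncoupling protein UCP3 at −1.54 called lower, and 6 higher and 2 lower adjusted over the list alone.

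Oxidative phosphorylation was lower in SS (median −0.23, 1 called, 10 adjusted over the list alone, adjusted p = 1.17e-12, and adjusted p = 0.295 with an estimated correlation), as was the TCA cycle (−0.23, 1 called, 3 lower and 1 higher adjusted over the list alone, adjusted p = 0.00458, and adjusted p = 0.295 with an estimated correlation), but the latter not with quantile normalization (−0.17). HDAC, MEF2 and calcium or cAMP signalling was higher (0.22, 2 called, 2 adjusted over the list alone, adjusted p = 0.0015, and adjusted p = 0.261 with an estimated correlation), the 2 called genes being STAC3 and RCAN1. Matrix genes were at −0.19 (1 called, 1 adjusted over the list alone, adjusted p = 0.0332, and adjusted p = 0.699 with an estimated correlation), a call lost without replicate 1 of SM NN T12 (−0.15), SS NN T12 (−0.20) or ST NN T12 (−0.18).

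Red blood cell markers were lower in SS (median −1.22, 0 called, 1 adjusted over the list alone, adjusted p = 0.0465, and adjusted p = 0.295 with an estimated correlation). With the array number as a block the median was −1.22 and the list did not pass. With an offset of 32 it was −0.41 and did not pass. It did not pass either without replicate 1 of SM NN T12 (−0.98), SS NN T12 (−0.78), ST NN T12 (−0.96) or LD NC T12 (−0.72), or without replicate 2 of LD NC T0 or LD NN T12 (−1.22 each). The ribosomal list was not called, with median and mean at −0.00 (test upward, adjusted p = 0.946), nor was the nerve list (median 0.10, mean −0.07, test upward, adjusted p = 0.695). The others not called were embryonic and neonatal muscle (0.26, 0.546), adipocyte (0.20, 0.215), endothelial (−0.22, 0.114) and immune cell markers (−0.11, 0.424), proliferation (−0.01, 0.86), protein breakdown (−0.08, 0.424), growth signalling (0.02, 0.867) and stress genes (0.10, 0.546), each with its median and adjusted p. The 3' to 5' GAPDH ratio was 0.0244 and 0.0583 on the SS arrays of NN and 0.113 to 0.222 on those of SM and ST, and it moves with each list change between these muscles. The actin ratio of SS in NN, 0.127 and 0.0881, lay inside the range of SM and ST (0.000228 to 0.190).

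To ask how far the callipyge difference in LD follows the difference between muscles, the T12 changes in LD were set against those of SS over SM and ST, which share no array. Across 15613 probe sets, which are not independent replicates, Pearson's r was −0.062 and Spearman's rho −0.071, and r was −0.185 over the 4369 probe sets with mean log2 signal above 8. Leaving out single arrays moved r from −0.0657 to −0.0450. Of the 28 callipyge calls 0 were also called on this axis, where 1889 probe sets had an unadjusted p under 0.05. With 0.439 expected from 10000 random lists of like signal, that count cannot show a shortfall. In the F test over muscles, which shares the LD arrays of the other genotypes with the callipyge comparison so that part of any excess may come from them, 2 of the 28 were called, METTL21E and PLCL2, against 0.589 expected (one-sided permutation p = 0.118 from the random lists). The sign was opposite for 16 of the 28. Slow-fibre genes, at −0.60 in CN and 0.34 in SS, and glycolysis genes, at 0.19 and −0.87, moved in opposite directions in the 2 comparisons, while oxidative phosphorylation was lower in both (−0.22 and −0.23). With an estimated correlation none of these passed, the adjusted p being 0.282 and 0.295 for slow-fibre genes, 0.385 and 0.261 for glycolysis and 0.385 and 0.295 for oxidative phosphorylation.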

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

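The list tests of the age interaction and of the LD and SS difference were chosen after the data were seen, as were all tests below except the correlation with the age step over all probe sets and the test of saturated probe sets. Between T0 and T12 the callipyge difference in LD moved upward for fast-fibre genes (median 0.25, adjusted p = 3.03e-05), glycolysis and glycogen (0.47, adjusted p = 6.92e-07), oxidative phosphorylation (0.28, adjusted p = 9.12e-14) and the TCA cycle (0.37, adjusted p = 3.03e-05), and downward for slow-fibre genes (−0.44, adjusted p = 8.69e-04). The adjusted p with an estimated correlation was 0.415 for each of the 5. Against SS, the callipyge difference in LD was lower for slow-fibre genes (−0.70, adjusted p = 1.68e-09), matrix and fibroblast markers (−0.47, adjusted p = 1.78e-07) and fatty acid genes (−0.26, adjusted p = 0.00203), and higher for protein breakdown (0.17, adjusted p = 0.00445), with an adjusted p = 0.493 with an estimated correlation for each. It was also lower for ribosomal proteins (−0.19, adjusted p = 7.81e-05, and 0.616 as the adjusted p with an estimated correlation) and oxidative phosphorylation (−0.12, adjusted p = 0.0278, and 0.739 as the adjusted p with an estimated correlation). In SS 5 of the 12 slow-fibre genes had a signal above 29547, the bound of the bright probe sets below, in 1 genotype or both, and saturation in the slow-fibre difference between LD and SS stays open. The 3' to 5' GAPDH ratio of CN in LD was 0.230 and 0.225 at T0 and −0.0332 and 0.0849 at T12. In SS it was −0.0273 and 0.0867 in CN and 0.0244 and 0.0583 in NN. The actin ratio of CN in LD overlapped between the ages (0.00873 and 0.223 at T0, 0.0473 and 0.0360 at T12). A part of RNA quality in the list changes above stays open. These gene lists drew attention because they passed between ages or muscles where 0 single probe sets did. The number of lists called for LD against SS fell from 6 to 3 without LD CN T12 replicate 2, and quantile normalization ended the calls of oxidative phosphorylation (−0.06) and ribosomal proteins (−0.05). In leave-one-out fits 4 of these 6 calls ended at least once. That of oxidative phosphorylation ended without replicate 2 of LD CN T12 (−0.06) or SS CN T12 (−0.05), or replicate 1 of LD NC T12 (−0.10), LD NN T12 (−0.09) or SS NN T12 (−0.09). Protein breakdown was at 0.08 without SS CN T12 replicate 1 and 0.12 without SS NN T12 replicate 2, fatty acid genes at −0.20 without LD CN T12 replicate 2, and ribosomal proteins at −0.12 without replicate 2 of either CN group at T12.

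MEG3 in LD of CN lambs lay above NN at both ages on 2 of 5 probe sets, and below NN on another that responds to genotype, although CN carries the mutation on the paternal allele. RNA of an NC or CC sample mixed into the CN sample could raise MEG3, and then all MEG3 probe sets would share 1 mixing share. Over all 5 probe sets 0 of 4 gaps between shares lay above 0, since 2 did not respond to genotype, and the test was restricted to the 3 responding ones after that first run. There the shares differed by at least 4.98 percentage points after 2 SD on each side, but that SD covers technical arrays only and the baseline comes from 1 NN sample, so mixing cannot be told apart from variation between samples. On the brightest probe set the lower CN array lay 1.33 log2 units above the higher NN array at the age with the smaller gap, but arrays here are technical repeats of 1 sample, so spread between samples cannot be told apart from an effect of genotype.

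Oxidative phosphorylation transcripts were lower in LD of CN newborns (median −0.48, adjusted p = 0.141 with an estimated correlation), as they were with age (adjusted p = 0.45 with an estimated correlation). If CN newborns were further along the course of age, the CN difference at birth would correlate with the age step, and r over 3 choices of genotype was 0.0187 to 0.0581 over all probe sets and 0.103 to 0.267 over those with mean log2 signal above 8. The age step of the list was −0.11 to −0.19, less than the CN difference of −0.44 to −0.48 in the same test, which a steady course of age would not give, but with no ages between T0 and T12 an uneven course cannot be told apart from a specific change. Degraded RNA in the CN birth sample also cannot be told apart, since 1 of its 4 log2 ratios of 3' to 5' signal, actin at 0.223, lay above the other birth arrays (up to 0.196), while actin at 0.00873 and GAPDH at 0.225 and 0.230 (others 0.131 to 0.307, the lower at −0.0825 from the highest) lay inside. The main direction of differences between the 2 arrays of a group, removed from every array and so from the group means, does not account for it, since the median was −0.49 afterwards. How far array scaling adds to the size of the list change stays open.

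Slow-fibre transcripts fell in LD of CN lambs at T12 (−0.60, adjusted p = 0.282 with an estimated correlation) without a called rise of fast-fibre transcripts (adjusted p = 0.161). Saturation of the brightest probe sets could hide such a rise: the SD of age changes over 15 bright probe sets was 11.5% (95% interval 7.70 to 14.3) of that over 640 of middle brightness. Of these 15 probe sets 7 measure genes of the fast-fibre list, so low true variation may produce the same 11.5%. The 3' to 5' GAPDH ratio was lower in CN (−0.0332 and 0.0849) than in NC and NN (0.187 to 0.246) but near that of CC (0.0433 and 0.0663). The actin ratio of CN (0.0473 and 0.0360) lay inside the range of NC and NN (0.0314 to 0.294). A part of RNA quality in the slow-fibre change stays open. MYH2 and MYH4 were not among the genes measured here. A quantitative PCR of MYH1, MYH2 and MYH4 with a standard curve would separate saturation from low variation.

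For the age comparison, 1831 probe sets were called with the real split and at most 0 with the others, so 1 of 10 splits had as many calls, and 10 splits are too few for a share under 0.05.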

How the results depend on the processing

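Changes of method moved the number of calls more than the direction of the genes, and the cause of each shift was not tested. Counts without an array of a group with a single value can be too high, since the SE misses the larger technical spread of the array that remains. In the order CN in LD at T12, CN in LD at T0, age, interaction, CN in SS, LD minus SS, the F test over muscles, SS against SM and ST, NC and CC, counting each array as a sample gave 514, 893, 3200, 387, 24, 37, 1317, 706, 7 and 61 calls. With the array number as a block they were 586, 978, 3305, 430, 26, 42, 1407, 791, 9 and 63. The block is 1 shift shared by all groups in the fit. The pairing found in the data ran in opposite directions between some groups (r down to −0.411), so the block takes up only its shared part. Of the list calls of the group means the block ended 1, that of red blood cell markers for SS against SM and ST (−1.22). With the block 10 lists were called at T12, 7 in SS, 6 for the interaction and 8 for LD minus SS, against 9, 6, 5 and 6 for the group means. Without it they were 10, 8, 6 and 8, so the block itself changed SS by 1 list and SS against SM and ST from 9 to 8. Arrays counted this way are technical repeats, so these counts overstate the evidence. Depth is limited by signal over background.

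Quantile normalization gave 11 calls for CN at T12 (3 higher, 8 lower) and 7 at T0 (5 and 2), called 9 lists for the interaction, moved r with the muscle axis to −0.0513, turned MEG3 in the interaction to −0.012 and turned ribosomal proteins at T0 to 0.063. It kept 62 of 84 called genes and 43 of 53 called lists. Without the filter there were 11 calls at T12, 4 for CC and r = −0.0186. The 75th percentile filter gave 13 at T12 (3 and 10), 82 at T0 (45 and 37) and r = −0.147.

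An offset of 32 gave 18 calls at T12 (7 and 11), 90 at T0 (60 and 30), 2 for the interaction, 4 for CC and r = −0.0947, and split SS against SM and ST into 107 higher and 76 lower. Without the intensity trend there were 0 calls at T12, 0 at T0, 239 for age, 1 in the F test, 4 for SS against SM and ST, 0 for NC and 0 for CC, and 10 of 84 named genes kept the call. Camera keeps its own trend, so lists were not run there. With only the groups compared there were 3 at T12, 6 at T0, 83 in the F test, 40 for NC and 4 for CC. CN in SS and SS against SM and ST could not be run there, because each group is then a cell of its own, SM and ST included, and no residual degrees of freedom remain.

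NN alone as comparator gave 52 calls at T12 (23 and 29), 108 at T0 (79 and 29), 694 for age, 14 for the interaction and 3 for LD minus SS. That fit keeps 1 residual degree of freedom, the difference between the age steps of CC and NC, so its counts rest on little measured spread. With NN alone MEG3 turned to 2.74 at T12, 1.46 at T0 and 2.13 for LD minus SS, and PPP2R5C to 0.20 for the last. Without CC the counts were 47, 273, 16 for the interaction and 1 for LD minus SS, with MEG3 at T12 at 0.15 and PPP2R5C for LD minus SS at 0.059. Without NC they were 0 at T12, 0 at T0, 392 for age and 65 in the F test, with MEG3 at T12 at 0.16. Without NN they were 8, 4, 713 for age and 2 for LD minus SS, with PPP2R5C at T12 at −0.14 and MEG3 in the interaction at −0.46. All 4 genotypes with genotype as a block gave 2276 calls for age.

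Other comparators ended list calls. NN alone ended those of ribosomal proteins at T12 (−0.08), T0 (−0.08) and for LD minus SS (−0.13), and of fast-fibre (−0.19) and glycolysis genes (−0.17) at T0. Without NN those of the TCA cycle (−0.14) and endothelial markers (−0.24) at T12, slow-fibre genes at T0 (−0.20), and oxidative phosphorylation (−0.11) and protein breakdown (0.14) for LD minus SS ended, and without NC that of oxidative phosphorylation for LD minus SS (−0.08). The 75th percentile filter ended proliferation for age (−0.30) and matrix genes for SS against SM and ST (−0.19), and signal over 8 also ended matrix genes there (−0.19), endothelial markers at T0 (−0.15) and stress genes in SS (0.22).

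With an estimated correlation 0 lists were called in each of the 7 comparisons, down from 53 in all. Chosen after the data were seen, keeping control probe sets gave 17 calls at T12, mean log2 signal over 8 gave 8 at T12, 66 at T0, 3 lists in SS and r = −0.185, and removing the first array component gave 67 at T0 and DLK1 in SS at −0.000948.

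Leaving out each of the 24 arrays gave, as lowest and highest, 1 and 414 calls at T12, 3 and 268 at T0, 1225 and 1910 for age, 0 and 37 for the interaction, 0 and 12 in SS, 0 and 2 for LD minus SS, 125 and 383 in the F test, 88 and 275 for SS against SM and ST, 2 and 2 for NC and 2 and 4 for CC. Lists called were 7 and 11 at T12, 7 and 13 at T0, 7 and 7 for age, 1 and 7 in SS, 7 and 11 for SS against SM and ST, 5 and 7 for the interaction and 3 and 6 for LD minus SS, and r ran from −0.0657 to −0.0450. Genes that turned at T12 were SHMT2 (−5.18 to 0.026), MPDZ (−5.76 to 0.65), TRAPPC9 (−4.46 to 0.19) and PPP2R5C (−0.21 to 0.23), and at T0 WARS1 (−0.29 to 0.0042). In the interaction these were MEG3 (−0.043 to 0.28) and PPP2R5C (−0.081 to 0.35), in SS MARS1 (−0.063 to 3.31), PPP2R5C (−0.13 to 0.35) and DLK1 (−0.082 to 0.090), for LD minus SS PPP2R5C (−0.34 to 0.14), and WARS1 for NC (−0.050 to 0.19) and CC (−0.060 to 0.38).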

Other observations

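The genes and values here were chosen only after the results were seen. FBXO32, a ubiquitin ligase of muscle protein breakdown, differed among newborns by genotype, with LD signals at T0 of 1949 in CN (arrays 1793.1 and 2118.7), 1167 in CC (1227.8 and 1109.9), 268.9 in NC (225.2 and 321.1) and 102.0 in NN (105.8 and 98.3). At T12 the LD values were 3825, 2381, 1734 and 2085, and SS had 4407 in CN and 3743 in NN. The genotypes with a paternal mutant allele, CN and CC, were the highest at birth, though each value is 1 group. Whether age within the first 5 days, feeding or handling differed between the lambs sampled was not tested. Measuring FBXO32 and TRIM63 in single newborns of known age and feeding time would separate genotype from age and fasting.

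XIST, the noncoding RNA of the inactive X chromosome, had LD signals at T0 of 160.8 in CC, 172.6 in NC, 64.5 in NN and 44.2 in CN, and 11.5 to 54.4 in the groups at T12. The protocol speaks of male lambs. The arrays at T0 gave 249.2 and 119.6 in NC, 163.5 and 158.2 in CC, 104.1 and 40.0 in NN and 48.2 and 40.5 in CN, against array medians of 47.4 to 52.9. Neither female lambs among the newborns nor cross-hybridization was tested. A Y-linked transcript measured in the same RNA would decide it.

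Spread between genotypes in LD exceeded what the technical arrays predict most for bright probe sets, with a variance ratio of 1.96 among the brightest of 4 equal classes of signal and 1.06 to 1.28 in the others. The first component within groups held 12.8% of the within-group sum of squares and correlated with the contrasts at 0.0329, 0.0489 and 0.120 in size for CN at T12, CN at T0 and age.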
